A study of Bacillus subtilis subsp. subtilis str. 168 with 18 samples.

How the data were processed

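Transcript levels of Bacillus subtilis 168 were measured on 18 macroarrays, 3 independent cultures in each of 6 groups. Wild-type cells with the empty plasmid pUB110, wild-type cells with pKTH10, and a cssS mutant with pKTH10 were each sampled in late exponential phase, 1 hour ahead of the transition point, and 3 hours into stationary phase. Plasmid pKTH10 directs high-level production of AmyQ, a secreted alpha-amylase of Bacillus amyloliquefaciens. Cells were grown in TY medium at 37 °C, and total RNA was copied into 33P-labelled cDNA with primers specific for the open reading frames, per the labels' protocols.

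The values used are the deposited intensity of each spotted gene, in percent of the array's total signal, on a linear scale. The authors averaged duplicate spots in Array-Pro, subtracted background and expressed the signal of each gene as a percentage of the total in Microsoft Excel, per the series description. The columns nevertheless summed to between 104 and 321, and, with the 80 brightest values of each array left out, to between 94.1 and 99.4. Which spots entered the authors' total is not given in the sources used here. The plan had been to rescale to a sum of 100 any table not scaled to its total. The deposited scaling was kept because the columns are already percentages by the authors' own total, and the rescaled version was run as an alternative. Keeping the deposited scaling for the main fit was thus a departure from the plan, made after the column sums were seen. Median values per array lay between 0.00771 and 0.0174 percent. Arrays give no counting depth, so the number of arrays limits the precision.

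The table held 4107 spotted genes, of which 3894 were in the probe table: 3862 had 1 gene symbol and 32 had several. Another 213 had no entry there, stay unnamed here and were not tested with the rest. Symbols were updated through the gene identifiers of assembly ASM904v1, of which 3848 matched, and the assembly was used for names alone. Spots with several symbols were tested but not named. Repeated entries of a gene were averaged, which merged 9; the lowest correlation between such entries was 0.022. This left 3885 genes.

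The 43 negative values were set to 0, an offset of 0.00243 percent (0.1 of the mean value per gene) was added, and log2 was taken. Linear models were fitted to all 18 arrays with group as the only factor in limma 3.58.1 (lmFit, eBayes; R 4.3.3), so that the 6 groups shared 1 estimate of spread per gene. P-values were adjusted by Benjamini-Hochberg over the genes of a comparison, with a threshold of 0.05. The 9 comparisons were AmyQ production and the cssS mutation in each growth phase, the difference of each of these effects between the phases, and stationary against late exponential phase in each strain.

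From 27 gene lists of pathways, regulons and structures, the 26 with at least 4 measured members were tested with limma's camera, two-sided, with a preset correlation between genes of 0.01, beside camera with an estimated correlation and fry. The list of autolysins of the SigD regulon had 3 measured members and was not tested. The lists of motility and of sporulation genes were included knowing that earlier work on the study treats these processes, so they are not an independent choice. Counts of list members past the threshold are given over all genes and adjusted over the list alone.

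The groups, tests, lists and naming rule were fixed before the data were examined. Named are cssS, cssR, htrA and htrB in every group. In each strain comparison, the 12 largest rises and 12 largest falls were named among genes past the threshold whose replicates did not overlap between groups; where fewer than 5 passed, the 10 with the smallest p were named. Up to 4 members with the smallest p were named per list described, and, between growth phases, the 5 largest changes each way among genes past the threshold, with overlap between replicates allowed.

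Replicate numbers were tested for pairing by correlating the deviations of same-numbered arrays from their group means, with pairing accepted where every pair exceeded 0.1. For AmyQ in late exponential phase the correlations were 0.692, 0.473 and 0.585 (pairs 1 to 3), for AmyQ in stationary phase 0.438, 0.632 and 0.44, and for cssS in late exponential phase 0.89, 0.634 and 0.581, so pairing was accepted for these 3 comparisons. All values are nevertheless from the fit with group as the only factor, and values with the replicate block are given where they change a call or a count by over 1.5-fold. The pairing comes from the data, since the labels give replicate numbers and state no shared day or batch.

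Alternatives were median centring, quantile normalization, offsets of 0.02 and 0.5 of the mean, removal of the dimmest 25% of genes (972), a trended robust prior, array weights, fits of the compared groups alone, a replicate block and leaving out each array. Rescaling to 100, the scaling foreseen in the plan, was run as an alternative too. Chosen after the data were seen were a replicate block within each growth stage, a term for the late arrays of replicates 2 and 3, inclusion of the unnamed spots and removal of 221 genes at or above 80% of the maximum of a narrow late array. Further such choices were the late arrays of replicates 2 and 3 alone, stationary pUB110 arrays 1 and 2 as one, removal of 6 arrays with a range under 6.5 log2 units, and the block within stages together with quantile normalization. A lone array left in a group was assumed to vary like the other groups.

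The fits were tested on simulated data with the real genes' levels and spread, in which 50 of 3885 genes were changed at each size. Recovery in percent for log2 changes of 1, 2, 3 and 4 was 6, 74, 96 and 98 for AmyQ in late exponential phase, and 18, 78, 86 and 94 for AmyQ in stationary phase. It was 20, 82, 94 and 100 for cssS in late exponential phase, and 18, 66, 92 and 90 for cssS in stationary phase. Simulated noise was independent between genes and arrays, without the deviations that same-numbered arrays share, and all sizes were changed together. Recovery in the real data may therefore be lower: htrA differed by 4.58 for AmyQ in late exponential phase and did not pass. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.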

Results

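The study asked how Bacillus subtilis responds to the stress of secreting large amounts of an alpha-amylase, AmyQ, and how far that response runs through CssS, the sensor kinase of the CssRS secretion stress system. Transcript levels came from 18 arrays, 3 cultures in each of 6 groups: wild type with the empty plasmid pUB110, wild type with the AmyQ plasmid pKTH10, and the cssS mutant with pKTH10, each in late exponential and in stationary phase. Values are percent of total signal, with mean ± SD, and differences are log2 ± SE from limma with n = 3 per group throughout. Stationary arrays correlated with each other at 0.751 to 0.983 across genes and with the late arrays at 0.382 to 0.756. The late exponential arrays formed 2 sets that the labels do not name: the 3 arrays of replicate 1 correlated with each other at 0.952 to 0.969 and with late replicates 2 and 3 at 0.642 to 0.756, although genes are not independent replicates. Each set held an array of every strain. In 6 arrays the range from the 1st to the 99th percentile was narrow: pUB110 late replicates 2 and 3 (4.65 and 4.15 log2 units), pUB110 stationary replicate 2 (5.11), pKTH10 stationary replicate 2 (5.85), and cssS stationary replicates 1 and 2 (4.72 and 6.21). The other 12 spanned 6.70 to 7.58. On the narrow pUB110 late arrays no gene exceeded 0.112 and 0.123 percent, so differences of bright genes against that group are affected by a ceiling.

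The mutated gene itself, cssS, did not separate the mutant from the wild type in late exponential phase, where 1 mutant array read high. In stationary phase all 3 mutant arrays lay below the 3 wild-type arrays with pKTH10 (-0.77 ± 0.44, not past the threshold). In wild type with pKTH10 it measured 0.0282% ± 0.00559 in late exponential phase and 0.0226% ± 0.00691 in stationary phase, against 0.0149% ± 0.00228 and 0.0124% ± 0.0041 with pUB110. In the mutant it measured 0.0187% ± 0.0179 and 0.0121% ± 0.00316. The 3 late mutant arrays read 0.0393%, 0.00686% and 0.00979%, and the first of these lay above all 3 wild-type pKTH10 arrays of that phase (0.0345%, 0.0238% and 0.0263%). Its neighbour cssR, encoding the response regulator, followed the same order of arrays, with 0.0216%, 0.00453% and 0.00597% on the late mutant arrays and 0.0165% ± 0.00377 in wild type with pKTH10. Whether the spotted cssS fragment lies in the disrupted part of the gene is not given in the sources used here. One array thus goes against its label, and it is called the array labelled cssS pKTH10 late replicate 1 throughout.

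The targets of CssR, htrA and htrB, encode membrane-anchored proteases that handle misfolded secreted proteins. In late exponential phase htrA measured 0.0463% ± 0.0318 with pUB110, 1.05% ± 0.517 with pKTH10 and 0.316% ± 0.46 in the mutant. The corresponding values of htrB were 0.026% ± 0.0062, 0.363% ± 0.127 and 0.133% ± 0.196. On the array labelled cssS pKTH10 late replicate 1, htrA stood at 0.846% and htrB at 0.36%, against 0.0295% and 0.0712% for htrA and 0.0168% and 0.0232% for htrB on the other late mutant arrays. In stationary phase htrA measured 0.0211% ± 0.0129, 0.186% ± 0.108 and 0.033% ± 0.0142 in the same order of strains, and htrB 0.0467% ± 0.0104, 0.09% ± 0.0264 and 0.0341% ± 0.00815.

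**Figure D1:**
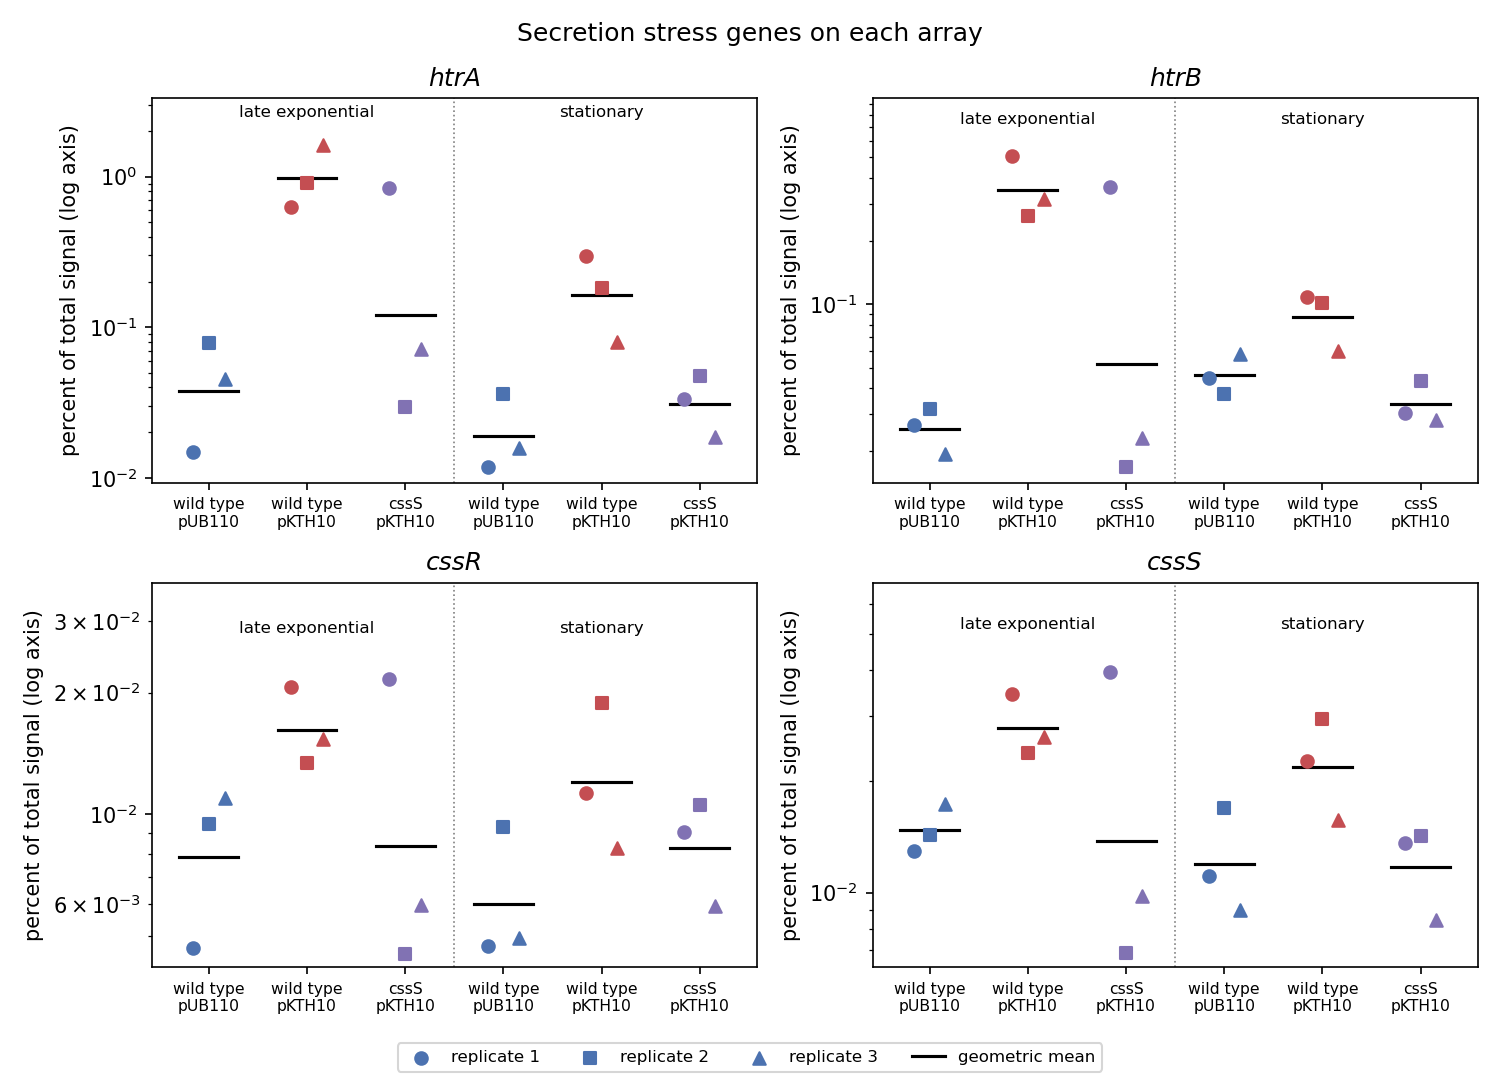
Signal of htrA, htrB, cssR and cssS on each of the 18 arrays, in percent of total signal on a log axis, by strain and growth phase; markers stand for replicates 1 to 3 and black bars for geometric means. The array labelled cssS pKTH10 late replicate 1 reads 0.846% for htrA, above the other mutant arrays and within the range of the wild type with pKTH10.

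AmyQ production in late exponential phase was the test for the secretion stress response in that phase. As a group, the 4 CssRS genes were higher with pKTH10 (median log2 difference 2.25, all 4 above 0; camera adjusted p = 6.9e-12, and 0.0182 with an estimated correlation), a call kept under all 25 alternatives. Within it, htrA differed by 4.58 ± 0.89 and htrB by 3.65 ± 0.73, 24-fold and 12.6-fold, with no overlap between the groups. Over all genes neither passed (adjusted p = 0.128 for both), while adjusted over the list alone both did, and all 4 members did with the block described next. With the replicate number as a block within each growth stage, a fit chosen after the data were seen, both passed (adjusted p = 0.0394 and 0.00915), and across all alternatives their adjusted p ranged from 4.6e-05 to 0.998 and from 2.97e-05 to 0.998. The kinase and regulator genes differed by less, cssR by 0.84 ± 0.44 and cssS by 0.81 ± 0.44 (adjusted p = 0.467 for both).

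In the same comparison 1 of 3885 genes passed, rpsB, which encodes ribosomal protein S2 (2.25 ± 0.32, adjusted p = 0.00718). It rose from 0.108% ± 0.0119 to 0.537% ± 0.155, but the pUB110 value lies at the ceiling of the narrow arrays, and with quantile normalization the difference was -0.73. The call was lost without pUB110 late replicate 2 (adjusted p = 0.0523), pKTH10 late replicate 2 (0.0797) or pKTH10 late replicate 3 (0.112), and its adjusted p ranged from 8e-06 to 1 over the alternatives. After rescaling, the scaling first planned, the call was lost as well. Without pUB110 late replicate 1, 20 genes passed, and with the block within stages 3 did, rpsB, htrA and htrB. With array weights 2160 passed (238 higher, 1922 lower), and with late replicates 2 and 3 alone 72. At an unadjusted p under 0.05 there were 328 genes, and in 545 (14%) the replicates of the groups did not overlap. Chance gives 10% if the arrays are interchangeable. Deviations shared within pairs, accepted for this comparison, lower that share, and a shift of all genes (median -0.46) raises it. The 14% therefore cannot be read against 10%. Other genes with the smallest p, none past the threshold (adjusted p = 0.467), were pdhD (1.61) and pdhC (1.55) of pyruvate dehydrogenase, ald (2.44), ahpF (1.47), rpoA (2.14), yosA (-1.23) and fabHB (-1.39). With quantile normalization pdhD read -0.88 and ahpF -0.24. All but yosA and fabHB of these lay near the ceiling. In pair 1, with the only wide pUB110 array, they differed by 0.03 for pdhD, -0.03 for pdhC, 0.06 for ald, 0.07 for ahpF and 0.18 for rpoA, and in pairs 2 and 3 by 2.10 to 3.86. Without pUB110 late replicate 1, which leaves the 2 narrow arrays, the adjusted p was 0.0343 for pdhD, 0.0138 for pdhC, 0.0146 for ald, 0.0249 for ahpF and 0.0138 for rpoA, and over the alternatives it ranged from 8e-06 to 1 among them.

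Gene lists for growth and metabolism stood above the rest in this comparison, in which the median of all genes was -0.46 and became 0.07 with median centring, 0.01 with quantile normalization and -0.77 after rescaling. Ribosomal protein genes had a median of 0.77 (49 of 50 above 0; adjusted p = 1.8e-37, and 0.0842 with an estimated correlation), which fell to 0.09 with quantile normalization and to -0.64 without the narrow arrays. Removal of the narrow arrays leaves pUB110 late replicate 1 alone in its group, against pKTH10 late arrays of both late sets. Adjusted over all genes and over the list alone, 1 member passed, and 12 over the list alone with the block within stages. Among its members were rpsF (1.28), rpsR (1.28) and rplJ (1.42), with adjusted p = 0.467. Genes of the TCA cycle had a median of 1.32 (9 of 10 above 0; adjusted p = 8.99e-12, and 0.0752 with an estimated correlation), 1 member passed when adjusted over the list alone (9 with the block within stages, 8 of them higher) and 0 over all genes, and the median was -0.38 once genes near the ceiling were left out. Their smallest p belonged to sucC (2.31), sdhB (1.33), odhB (1.32) and icd (1.94). All 7 of these named genes lay near the ceiling. With only the 2 narrow pUB110 arrays left, without late replicate 1, rpsF, rpsR, rplJ and sucC passed (adjusted p = 0.0424, 0.0138, 0.0249 and 0.00689), while in pair 1, with the wide pUB110 array, they differed by 0.22, -0.15, -0.07 and -0.02. Respiration and ATP synthase genes had a median of 0.41 (adjusted p = 7.93e-13, and 0.12 with an estimated correlation), and -0.34 without the narrow arrays.

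Chaperones and proteases of protein quality control, a list fixed without htrA and htrB, were also higher relative to all genes (median 0.28, 12 of 18 above 0; adjusted p = 1.3e-07, and 0.0182 with an estimated correlation). The list held groEL (1.23), tig (1.28), dnaK (0.81) and lonB (-0.81), of which none passed alone (adjusted p = 0.467). Glycolysis genes were called higher as well (median 0.24, 8 of 12 above 0; adjusted p = 9.38e-06, and 0.0182 with an estimated correlation). The lists parted in pair 1, the only one whose pUB110 array has a wide range: less all genes, quality control stood at 0.29 and glycolysis at -0.27. In pairs 2 and 3, with narrow pUB110 arrays, quality control stood at 0.80 and 1.15 and glycolysis at 0.98 and 1.21, so that glycolysis followed the order of the ribosomal protein list (-0.24, 2.08 and 2.02). With quantile normalization the medians were 0.17 and -0.15 and neither list passed (adjusted p = 0.175 and 0.526). After rescaling, with all genes at -0.77, they were -0.19 and -0.23. Over the alternatives the adjusted p ranged from 4.74e-09 to 0.175 and from 3.57e-07 to 0.571.

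In stationary phase lists of sporulation and spore coat genes were lower and the list of motility genes higher with pKTH10, by camera with the preset correlation. With an estimated correlation none of the 3 passed (adjusted p = 0.106, 0.313 and 0.106), and over all genes 0 of their members did. Of 3885 genes, 6 passed, 2 higher and 4 lower. The 4 that fell belong to mother-cell metabolism: mmgD (-2.09 ± 0.33, adjusted p = 0.0152) and mmgE (-2.24 ± 0.41, 0.0329) of the methylcitrate pathway operon, and ldeG (-1.96 ± 0.37, 0.0329) and ldeI (-2.15 ± 0.37, 0.0244) of leucine degradation. For mmgD this was a fall from 0.167% ± 0.0901 to 0.0348% ± 0.00896. The risers were fbnA, named for a fibronectin-binding protein (3.17 ± 0.48, 0.014; from 0.00772% ± 0.00313 to 0.086% ± 0.00615), and ykoJ (2.29 ± 0.40, 0.0244). Of the CssRS genes, htrA differed by 2.94 ± 0.89 (adjusted p = 0.266), htrB by 0.89 ± 0.73 (0.824), cssR by 0.78 ± 0.44 (0.675) and cssS by 0.76 ± 0.44 (0.705). The list of 4 had a median of 0.83 (adjusted p = 0.014, and 0.59 with an estimated correlation), with 1 member higher when adjusted over the list alone and 0 over all genes, and it was lost without pUB110 stationary replicate 3 (0.0902) or pKTH10 stationary replicate 1 (0.066), and without the narrow arrays (0.0786).

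The stationary count rested on single arrays: 0 genes passed without pUB110 replicate 1, pKTH10 replicate 2 or pKTH10 replicate 3, 2 without pUB110 replicate 2, and 227 (34 higher, 193 lower) without pUB110 replicate 3. Without pKTH10 replicate 1, 4 passed, ykoJ and ldeG being lost (adjusted p = 0.143 for both). All 6 genes kept their direction under every alternative run. Their adjusted p ranged from 0.000146 to 0.974 for fbnA and from 0.000313 to 0.974 for mmgD, with the other 4 inside 0.000604 to 0.974. With the replicate block within each stage 124 genes passed (21 higher, 103 lower), with quantile normalization 41 (9 higher, 32 lower), with array weights 220 (36 higher, 184 lower), with median centring 4 (2 higher, 2 lower) and after rescaling 0. A fit of the compared groups alone gave 3, all higher, the lowest offset 1 and removal of the narrow arrays 0. Replicates 1 and 2 of stationary pUB110 correlated at 0.983 with each other and at 0.813 and 0.809 with replicate 3, and taken as one array they gave 2 genes (1 higher, 1 lower). At an unadjusted p under 0.05 there were 341 genes, and 406 (10.5%) did not overlap between the groups. Chance gives 10% if the arrays are interchangeable, and less with the deviations shared within pairs that were accepted here. The median of all genes was 0.17, and 0.04 after rescaling.

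Sporulation regulators and stage-specific genes had a median of -1.09 (43 of 46 below 0; adjusted p = 6.41e-18, and 0.106 with an estimated correlation). Adjusted over the list alone, 1 member was lower, and 0 over all genes. The members with the smallest p were spoIVCA (-2.01, adjusted p = 0.118), which encodes the recombinase that assembles the sigK gene, spoIIID (-2.21, 0.229), spoIVFA (-1.06, 0.266) and spoIIE (-1.17, 0.266). Spore coat and spore protein genes had a median of -1.10 (32 of 38 below 0; adjusted p = 1.16e-13, and 0.313 with an estimated correlation). In that list 9 members were lower when adjusted over the list alone and 0 over all genes, led by cotJB (-2.25, 0.0911), cotE (-1.92, 0.232), sspB (-3.12, 0.239) and cotJC (-1.74, 0.257). Flagella and chemotaxis genes had a median of 0.91 (53 of 55 above 0; adjusted p = 2.36e-17, and 0.106 with an estimated correlation). Their count was 17 higher when adjusted over the list alone and 0 over all genes, led by the basal body genes fliF (1.95, 0.069), flgC (1.75, 0.0911), fliG (1.55, 0.125) and fliE (1.38, 0.148). With the block within stages the counts over all genes were 8 lower, 11 lower and 12 higher in these lists, and adjusted over the list alone 25 lower, 21 lower and 41 higher.

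Those single-gene calls depended on pUB110 stationary replicate 3, without which fliF, flgC, fliG and fliE passed (adjusted p = 0.00341, 0.00341, 0.00388 and 0.0225). So did spoIVCA, spoIIID and spoIVFA (0.0016, 0.00334 and 0.00863), and cotJB, cotE, sspB and cotJC (0.0024, 0.00555, 0.00152 and 0.00367). With the block within stages fliF, flgC, fliG and fliE passed (0.00988, 0.0136, 0.0107 and 0.0205), as did spoIVCA, spoIIID and spoIIE (0.00337, 0.0175 and 0.0458) and cotJB, cotE, sspB and cotJC (0.00988, 0.0416, 0.00226 and 0.0458). Over the alternatives the adjusted p of these genes ranged from 0.000774 to 1. Each of the 3 list medians kept its sign with median centring, quantile normalization and rescaling. Sporulation regulators stood at -0.64 without pUB110 stationary replicate 1, and spore coat genes at -0.66 without pUB110 stationary replicate 2 and at -0.59 with the largest offset. Ribosomal protein genes were higher in this comparison (median 0.52, 50 of 50 above 0; adjusted p = 0.000414, and 0.814 with an estimated correlation), with the call lost without pUB110 stationary replicate 2 (0.445).

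**Figure D2:**
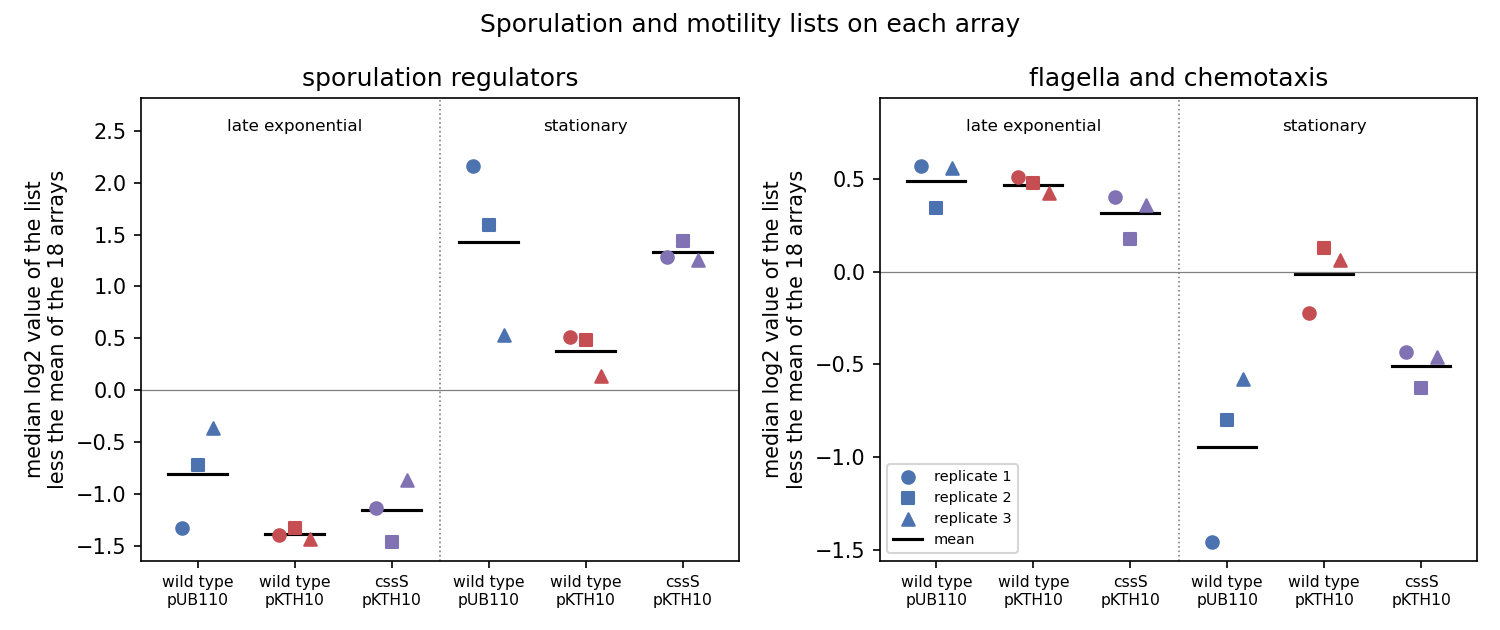
Median over list members of the log2 signal on each array, less the mean of the 18 arrays, for sporulation regulators (46 genes) and flagella and chemotaxis genes (55 genes), by group; markers stand for replicates and bars for group means. In stationary phase the AmyQ difference has a median of -1.09 for the first list and 0.91 for the second.

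The cssS mutation in late exponential phase tests which changes under AmyQ production need the kinase. The CssRS list was lower in the mutant (median -1.75, all 4 below 0; adjusted p = 6.32e-13, and 0.0378 with an estimated correlation), a call kept under all 25 alternatives. This list includes cssS, the mutated gene, and its neighbour cssR, so part of the fall may follow from the mutation itself. Its members htrA (-2.95 ± 0.89) and htrB (-2.64 ± 0.73) did not pass over all genes (adjusted p = 1), and both were lower when adjusted over the list alone. The values carry the array labelled cssS pKTH10 late replicate 1. Without it htrA differed by -4.33 (adjusted p = 0.0126) and htrB by -3.98 (4.23e-05), and these were the 2 genes past the threshold. Leaving out each array was planned, but this array stands out by its high htrA and htrB. Its removal therefore had to enlarge their fall, and these p-values are not an independent test. Over the alternatives the adjusted p ranged from 0.00135 to 1 for htrA and from 4.23e-05 to 1 for htrB. Both cssS (-0.85 ± 0.44) and cssR (-0.73 ± 0.44) had an adjusted p of 1.

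Across all genes of that comparison limma called 0, with 33 at an unadjusted p under 0.05 and 164 (4.22%) without overlap between the groups. Chance gives 10% if the arrays are interchangeable. Deviations shared within pairs, accepted for this comparison, lower that share, so the 4.22% cannot be read as a shortfall. Besides htrA and htrB, the smallest p belonged to yorO (1.81), mtlD (1.19), ysdB (1.19), pksR (1.32), yorZ (1.16), yjoB (1.17), ybfO (1.41) and ybbU (0.78), all at an adjusted p of 1. Genes of the SigW regulon and other cell envelope stress genes, among them ydjI (1.27), ythP (0.94), ysdB and yjoB, had a median of 0.82 (39 of 41 above 0; adjusted p = 3.59e-17, and 0.184 with an estimated correlation). In this list 0 members passed over all genes or adjusted over the list alone, and with the block within stages 6 were higher when adjusted over the list alone. The shift was uneven between pairs. Less all genes, the list stood at -0.09 in pair 1, which holds the array labelled cssS pKTH10 late replicate 1, and at 1.68 and 0.68 in pairs 2 and 3. The call was lost without cssS pKTH10 late replicate 2 (median 0.40, adjusted p = 0.117). Genes of the secretion machinery had a median of -0.28 (adjusted p = 6e-06, and 0.184 with an estimated correlation) and those of ATP synthase and respiration -0.39 (7.12e-13, and 0.184). Spore coat genes (median 0.23) passed with the block within stages (adjusted p = 0.0361) and not without it (0.112). The median of all genes was 0.13, and -0.07 with median centring and -0.03 with quantile normalization.

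In stationary phase the 3 lists that had differed between the plasmids stood the other way in the mutant, a comparison that shares the pKTH10 arrays, and again none passed with an estimated correlation. Flagella and chemotaxis genes had a median of -0.63 (48 of 55 below 0; adjusted p = 1.28e-15, and 0.143 with an estimated correlation), with flgC at -1.25, fliF at -1.15, fliL at -1.23 and motB at -0.88. Sporulation regulators had a median of 0.97 (44 of 46 above 0; 6.39e-15, and 0.186), with spoIVFA at 1.25, spoIVCA at 1.67, spoIIID at 1.95 and spoVE at 1.18. Spore coat genes had a median of 0.78 (36 of 38 above 0; 1.07e-10, and 0.317), with cotJB at 2.00, cotJC at 1.70, cotE at 1.75 and gerQ at 1.97. Over all genes 0 members of these lists passed, and adjusted over the list alone 1 coat gene was higher. The medians kept their signs under every alternative, but not their sizes. Without the narrow arrays, which include 2 of the 3 mutant arrays, they were -0.38 for flagella, 0.83 for sporulation regulators and 0.13 for spore coat genes (adjusted p = 0.00355, 3.84e-17 and 0.0014). The flagella median was -0.17 after rescaling, and with the largest offset it was -0.37 and that of coat genes 0.37. The CssRS list had a median of -1.05, and -0.52 after rescaling (adjusted p = 0.000462, and 0.317 with an estimated correlation), with htrA at -2.31 ± 0.89 (0.666), htrB at -1.32 ± 0.73, cssS at -0.77 ± 0.44 and cssR at -0.44 ± 0.44 (adjusted p = 1 for the last 3). Here too the list includes cssS, the mutated gene.

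No single gene passed there: limma called 0, with 218 at an unadjusted p under 0.05 and 453 (11.7%) without overlap, where chance gives 10% if the arrays are interchangeable. With quantile normalization 14 passed, with the block within stages 28 and with a fit of the compared groups alone 57. The smallest p belonged to ykoJ (-2.03 ± 0.40, adjusted p = 0.367). After it came lonB (1.49), a protease gene of the forespore, mmgD (1.38), scoA (1.75), yjbA (1.49), cotJB, sleL (1.58) and pdaB (1.21) of spore cortex turnover, spaD (2.15) and spoIVFA, all at an adjusted p of 0.382. The median of all genes was 0.04, and 0.40 after rescaling, -0.12 with median centring and -0.06 with quantile normalization.

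**Figure D3:**
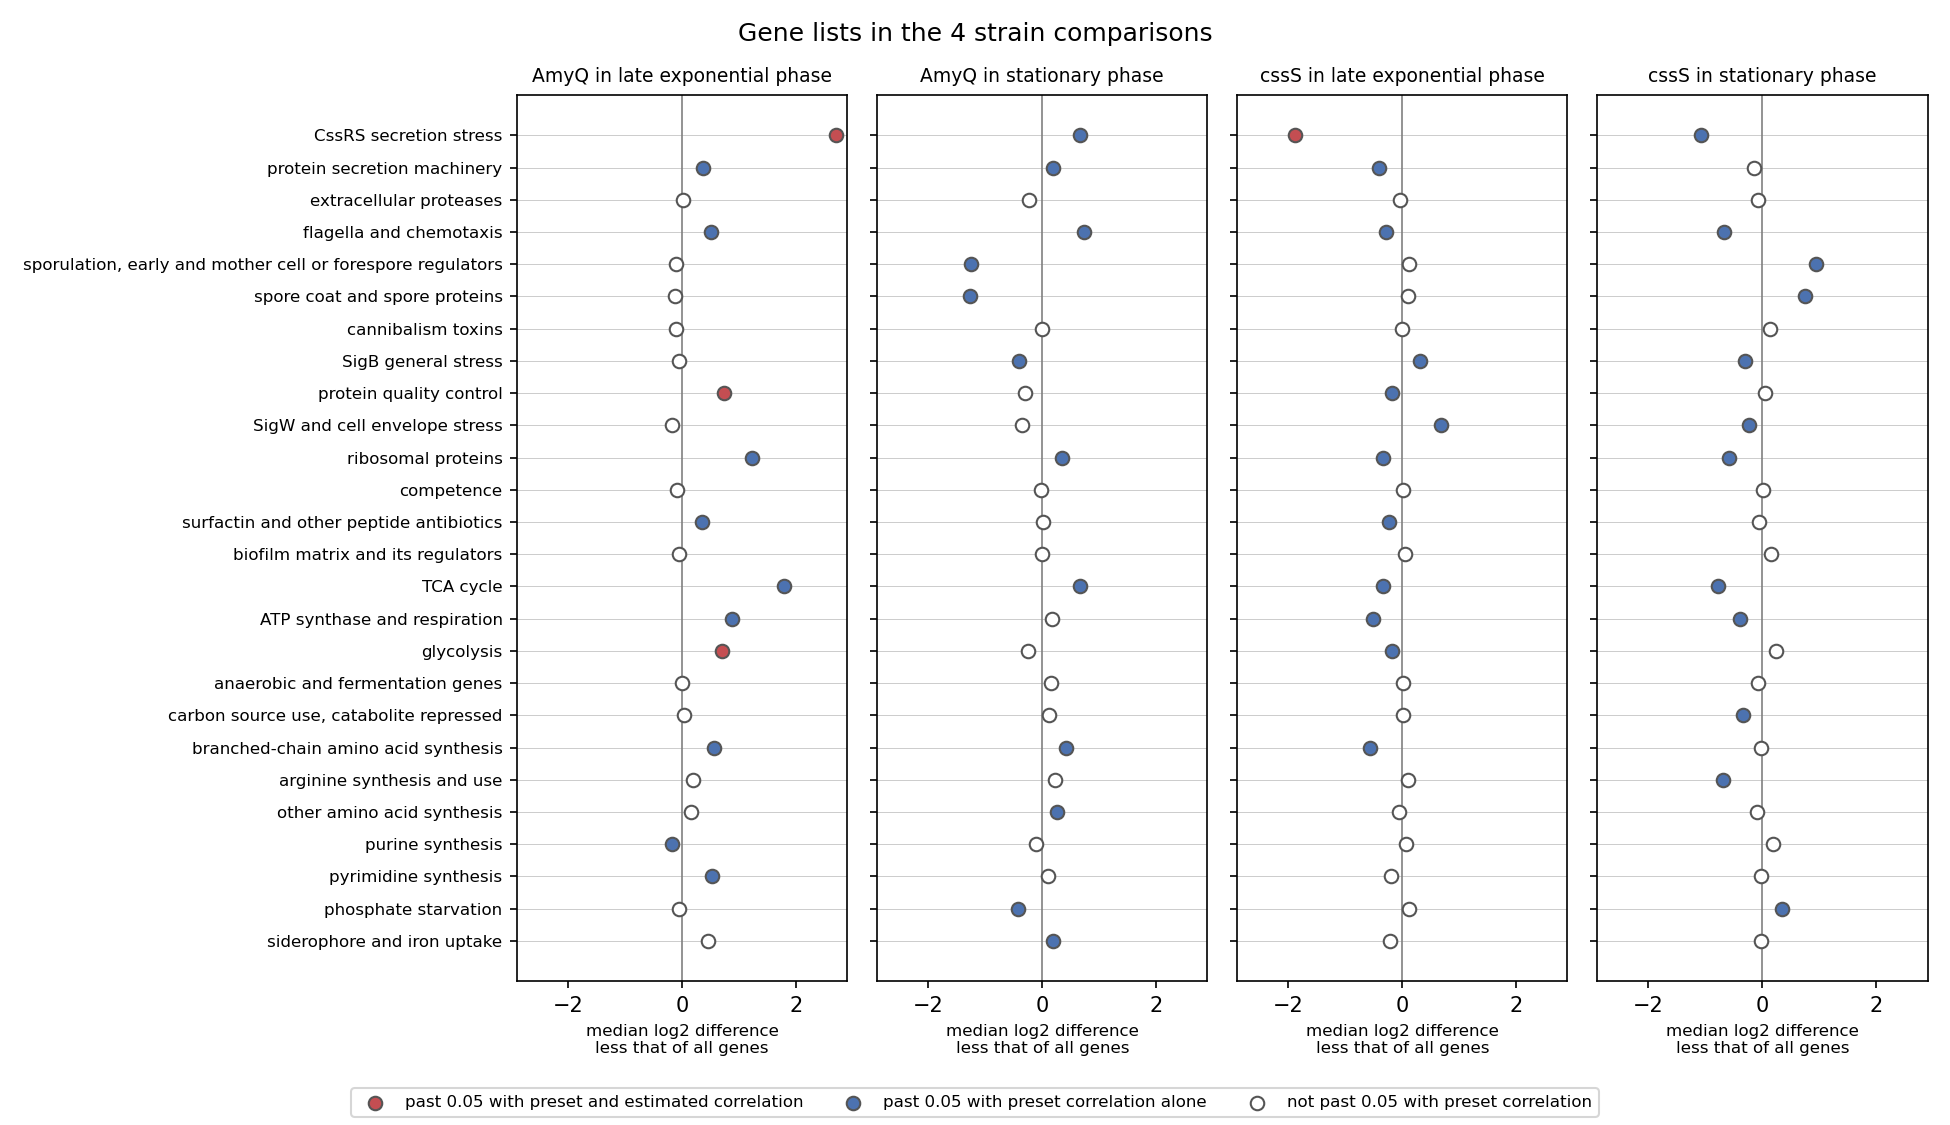
Median log2 difference of 26 gene lists, less the median of all genes, in the 4 strain comparisons; red marks lists past an adjusted p of 0.05 in camera with the preset and the estimated correlation, blue those past it with the preset alone, and white the rest. The CssRS list is red for AmyQ and for cssS in late exponential phase, and 4 of 48 calls are red.

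The AmyQ and cssS effects ran opposite to each other across genes, in part because each pKTH10 array enters both with opposite sign. Across genes, which are not independent replicates, the effects correlated at -0.68 in late exponential phase (Spearman -0.76) against -0.50 in 100 simulations with unchanged groups on shared arrays. In stationary phase the correlation was -0.80 (Spearman -0.70) against a simulated -0.50. The covariance in late exponential phase was -0.137 against -0.129 in these simulations, a difference of -0.0084. They treat the groups as independent, while deviations shared by arrays of the same number cancel within pairs. With such deviations kept, 100 simulations gave mean correlations of -0.32 and -0.31. For the covariance in late exponential phase their mean was -0.0343 (-0.0581 to -0.009), a difference of -0.103, so its excess depends on how the pairing is treated. In stationary phase, where pairing did not hold for cssS, it was -0.227 against -0.036 (-0.073 to 0.0033) with these deviations and -0.128 with independent groups, differences of -0.191 and -0.0995. Opposite signs held for 79.2% and 70.7% of genes, against 66.8% and 66.7% simulated with independent groups. In late exponential phase the median of all genes was -0.46 for AmyQ and 0.13 for cssS, while the simulated groups were unchanged. The 79.2% may therefore in part reflect this shift. The 3 shared arrays per phase cannot be halved with 2 in each part, so part of the excess may come from them.

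Tests of the difference between phases found 0 genes for the AmyQ effect and 0 for the cssS effect with limma, with 284 and 36 at an unadjusted p under 0.05. The change of htrA was -1.64 ± 1.26 (adjusted p = 0.577) and that of htrB -2.77 ± 1.03 (0.545) for AmyQ, and 0.64 ± 1.26 and 1.32 ± 1.03 (adjusted p = 1) for cssS. Without cssS pKTH10 late replicate 2 the change of htrA for cssS was -0.35. The median of all genes was 0.52 for AmyQ (-0.09 with median centring, 0.08 with quantile normalization, 0.72 after rescaling) and -0.09 for cssS (0.22 after rescaling).

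Entry into stationary phase changed more genes than either strain difference, except with array weights. There AmyQ in late exponential phase gave 2160, against 1616 for growth phase with pUB110, 2106 with pKTH10 and 1036 in the mutant. In wild type with pUB110 828 of 3885 passed (373 higher, 455 lower), in wild type with pKTH10 839 (575 higher, 264 lower) and in the mutant 795 (551 higher, 244 lower). Sporulation regulators rose in each strain (medians 2.24, 1.86 and 2.28; 33, 29 and 36 of 46 members past the threshold over all genes), with camera adjusted p of 1.84e-21, 1.07e-08 and 3.32e-16. Genes of cannibalism toxins (medians 1.11, 1.96 and 2.18; adjusted p = 0.00393, 0.00214 and 0.000608), extracellular proteases (0.88, 1.41 and 1.23; 0.0101, 0.00997 and 0.0155) and arginine metabolism (2.25, 1.93 and 1.12; 0.000516, 0.00032 and 0.0241) were higher as well. Ribosomal protein genes were lower (medians -1.64, -1.83 and -2.12; 3.09e-08, 6.35e-23 and 9.48e-25), as were flagella and chemotaxis (-1.39, -0.40 and -0.86; 3.24e-10, 4.51e-06 and 3.35e-11) and purine synthesis (-1.62, -0.69 and -0.72; 7.69e-06, 4.24e-05 and 0.000112). Spore coat genes had medians of 1.00, 0.64 and 1.05 (2.11e-06, 0.0813 and 0.00027), and glycolysis of -0.86, -1.60 and -1.13 (0.0417, 6.34e-06 and 0.00056). With an estimated correlation only the fall of glycolysis in wild type with pKTH10 passed among these lists (0.0286). All of these medians kept their sign with median centring, quantile normalization and rescaling, although rescaling moved the median of all genes with pUB110 from -0.23 to -0.71. Their sizes and some calls moved. After rescaling the medians with pUB110 were 0.20 for extracellular proteases, 0.40 for spore coat genes and 0.45 for cannibalism toxins. With pKTH10 spore coat genes passed with median centring (0.16, adjusted p = 0.0352) and after rescaling (0.33, 0.0145), and flagella stood at -0.87 with median centring. The glycolysis call with pUB110 was lost with median centring (0.0827).

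The balance of rises and falls depended on the scaling. With pUB110 it was 474 to 387 with median centring and 121 to 454 after rescaling. With pKTH10 it was 309 to 533 with median centring, 442 to 460 with quantile normalization and 112 to 167 after rescaling. In the mutant it was 345 to 511 with median centring and 543 to 543 with quantile normalization. The median of all genes was 0.41 with pKTH10 (-0.06, -0.05 and 0.15 with centring, quantile normalization and rescaling) and 0.25 in the mutant (-0.19, -0.13 and 0.27). Fewer genes passed with pUB110 without late replicate 2 (551) or stationary replicate 1 (375). With pKTH10 the counts were 449 and 448 without late replicate 2 or 3, and 488 and 520 without stationary replicate 1 or 2. In the mutant they were 467 without late replicate 2, and 522 and 453 without stationary replicate 1 or 2.

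Among single genes narH, a nitrate reductase subunit gene, had the largest rise in every strain (9.94 ± 1.37, 11.13 ± 1.37 and 9.53 ± 1.37), followed with pUB110 by sirB (9.21 ± 1.85), ppsC of plipastatin synthesis (8.10 ± 1.72), yqhQ (7.46 ± 2.00) and the coat gene cotNE (5.93 ± 0.96). These values depend on the offset, since 3 late arrays read 0 for narH, 2 for sirB, 1 for ppsC and 2 for yqhQ. On the narrow pUB110 late replicates 2 and 3, ppsC (0.0883% and 0.108%) and yqhQ (0.107% and 0.116%) also lay near the ceiling. In stationary phase narH, sirB, ppsC and yqhQ reached 50.6, 37.9, 36 and 19.6 percent. There sirB stood at 0.749 to 0.989 and ppsC at 0.711 to 0.943 of narH on every array, and yqhQ more loosely at 0.386 to 0.86. The positions of the spots on the filter are not given in the sources used here. Whether each reports its own transcript, or signal spreading from 1 bright spot, is therefore open for all 4. On pKTH10 late replicate 1 sirB, ppsC and yqhQ read 4.96, 4.71 and 4.00 percent with narH at 0. The rise of yqhQ did not pass without pUB110 late replicate 1 (adjusted p = 0.0535) or stationary replicate 1 (0.0653; range over alternatives 0.000504 to 0.0866). With pKTH10 the largest rises after narH were sirB (6.29 ± 1.85), whose late replicate 1 lay above stationary replicate 2 (1.42%), argC of arginine synthesis (5.74 ± 0.80), cotNE (5.23 ± 0.96) and the signalling peptide gene phrA (4.71 ± 0.87). In the mutant they were sirB (8.37 ± 1.85), cotNE (5.09 ± 0.96) and the coat assembly genes safA (5.04 ± 0.57) and spoIVA (4.93 ± 0.60). Late replicate 1 arrays differed by 0 between strains for argC and cotNE, as for narH, which read 0 there. The rises of argC and cotNE may thus depend on the offset too. Over the alternatives they ranged from 4.32 to 7.37 and from 3.92 to 6.85 with pKTH10. The largest falls with pUB110 were yvbJ (-3.56 ± 0.54), yxkC (-3.18 ± 0.51), the flagellar switch gene fliY (-3.02 ± 0.46), ydjH (-2.97 ± 0.60) and sunT (-2.84 ± 0.43). Of these yvbJ and ydjH lay near the ceiling of the narrow late arrays, so their size and rank are limited by it. With pKTH10 and in the mutant they included alanine dehydrogenase ald (-3.83 ± 0.63 and -4.19 ± 0.63), sucC (-3.43 ± 0.69 and -3.92 ± 0.69), ypwA (-3.74 ± 1.11 and -3.57 ± 1.11) and menD of menaquinone synthesis (-3.50 ± 0.99 and -3.25 ± 0.99), beside yvbJ with pKTH10 (-3.31 ± 0.54) and the chemotaxis gene cheV in the mutant (-4.75 ± 1.56). Both ald and sucC lay near the ceiling of the narrow pUB110 late arrays. Their falls with pUB110 are therefore capped and cannot be ranked beside these. The same may hold for ypwA, menD and cheV. Against the narrow pUB110 arrays (pairs 2 and 3) their late AmyQ differences were 2.4 and 2.6, 1.1 and 1.6, and 4.0 and 4.4. In pair 1 these differences were -0.3, -0.3 and -0.2. Large falls of these 3 genes are thus not shown to be particular to the strains with pKTH10. The arrays labelled cssS pKTH10 late replicates 1 to 3 read 0.0223%, 2.60% and 2.75% for cheV. Without the narrow arrays yvbJ (-2.97, adjusted p = 0.102), fliY (-2.97, 0.0699) and ydjH (-2.27, 0.24) no longer passed with pUB110, nor sirB in the mutant (10.75, 0.0721), with fewer arrays.

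Several of these changes did not hold when single arrays were left out. The rise of sirB with pKTH10 was lost without late replicate 2 (adjusted p = 0.117) or 3 (0.112) and without stationary replicate 1 (0.0938) or 3 (0.079), within a range of 3.94e-06 to 0.117. In the mutant cheV gave 0.187 and 0.158 without late replicates 2 and 3, and 0.0882, 0.112 and 0.0739 without stationary replicates 1 to 3, within 1.38e-10 to 0.463. In wild type with pKTH10 the adjusted p of ypwA was 0.117 and 0.121 without late replicates 2 and 3, and 0.0667, 0.0544 and 0.0645 without stationary replicates 1 to 3, and that of menD was 0.0886 and 0.106, and 0.0685 and 0.0571 without stationary replicates 1 and 2. In the mutant ypwA gave 0.149, 0.127, 0.0758, 0.0884 and 0.0651 without late 2, late 3 and stationary 1 to 3, and menD 0.122, 0.123, 0.068, 0.084 and 0.0613. The range over all alternatives reached from 2.34e-09 to 0.419 for ypwA and from 1.61e-07 to 0.391 for menD. With a term for the late array set the differences in the mutant were -1.35 for cheV, -1.13 for ypwA and -1.06 for menD (0.185, 0.113 and 0.0922). In wild type with pKTH10 htrA was lower in stationary phase (-2.56 ± 0.89, adjusted p = 0.0486), and htrB differed by -1.97 ± 0.73 (0.0613). The htrA call was lost without late replicate 2 (0.109) or 3 (0.167) and without stationary replicate 1 (0.0593), 2 (0.101) or 3 (0.167), within a range of 0.0006 to 0.177.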

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

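Chosen only after the result was seen were the tests of a swap, of high htrA on all late replicate 1 arrays, and of the narrow arrays on the ribosomal list and on rpsB, and also the counts over other splits of the arrays and of lists along a delay. The tests of a wrong label, of the narrow stationary arrays and of a delayed culture were set up before their results were seen.

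Gene lists are given here because their response differed between growth phases, by a test of the difference itself. The test is relative to all genes. The values printed are list medians, not less the median of all genes, which was 0.52 for AmyQ and -0.09 for cssS. By this test the AmyQ effect was lower in stationary than in late exponential phase for the CssRS list (-0.85, adjusted p = 0.00285), protein quality control (-0.52, 1.13e-07), sporulation regulators (-0.41, 9.05e-10), spore coat (-0.40, 1.64e-07) and ribosomal proteins (-0.21, 6.86e-09). The same held for the TCA cycle (-0.46, 0.0218), ATP synthase and respiration (-0.20, 9.32e-05) and glycolysis (-0.28, 0.000289). It was higher for flagella and chemotaxis (0.91, 0.000443) and competence (0.80, 0.0294). For general stress genes of SigB the median was 0.18, below the median of all genes (0.52), and the test read it as lower (0.023). With an estimated correlation only protein quality control passed (0.0403), glycolysis coming next (0.0566). The late part of the difference includes the narrow pUB110 late arrays, whose ceiling affects bright genes. In pairs 1 to 3 the late effect, less all genes, was 0.29, 0.80 and 1.15 for quality control and -0.27, 0.98 and 1.21 for glycolysis. For ribosomal proteins it was -0.24, 2.08 and 2.02, and for the TCA cycle 0.01, 2.21 and 2.86. Differences of these lists between phases cannot be told apart from the ceiling. The CssRS list stood at 2.9, 2.4 and 3.0.

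The cssS effect was higher in stationary phase for sporulation regulators (0.55, adjusted p = 4.81e-09), spore coat (0.45, 6.04e-06), protein quality control (0.18, 0.0337) and glycolysis (0.34, 0.0438). It was lower for the SigW list (-0.94, 7.14e-15), arginine metabolism (-0.91, 0.000205), SigB general stress (-0.62, 5.05e-05), flagella and chemotaxis (-0.44, 8.25e-05) and carbon source use (-0.41, 0.000102). None of these passed with an estimated correlation (smallest adjusted p = 0.353). The SigW list had been 0.82 higher in the late exponential mutant and was -0.19 in the stationary mutant, a value lost without pKTH10 stationary replicate 3 (0.19, adjusted p = 0.969) or cssS stationary replicate 1 (-0.21, 0.0545).

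Signal was also seen in the 213 spotted genes that have no name here and were outside the comparisons. Fitted with the rest, 46 of them passed between growth phases with pUB110, 51 with pKTH10 and 42 in the mutant, and 0 in any strain comparison by limma. Of the 3885 genes tested, 828, 839 and 795 passed between growth phases, a similar share. The counts thus do not set the unnamed spots apart. Which genes they are is not given in the sources used here.

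The first pattern weighed is the high htrA and htrB on the array labelled cssS pKTH10 late replicate 1. A swap with the wild-type array of the same number would put a low htrA there, and that array read 0.626%, while a general excess on late replicate 1 arrays would show with pUB110, which read 0.0149%; both values argue against these explanations. A wild-type sample under the mutant label cannot be told apart from a mutant culture that kept its response: outside the CssRS list the mutant difference of pair 1 correlated at 0.235 with the mean of pairs 2 and 3. The bound set in advance was a share of the correlation between pairs 2 and 3, and this was only 0.036, too low to decide. The SigW list, less all genes, was -0.09 in pair 1 and 1.68 and 0.68 in pairs 2 and 3, and a wrong label, an added wild-type sample or a biological difference of that culture may each remain.

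The second pattern is the higher ribosomal protein genes with AmyQ in late exponential phase. In pair 1, where both arrays had a wide range, their median less that of all genes was -0.24, against 2.08 and 2.02 in the pairs with a narrow pUB110 array. The narrow range of pUB110 late replicates 2 and 3 may therefore account for the list. Pair 1 is also the only pair from the late replicate 1 set, so the pairs cannot tell the range apart from the array set. For rpsB pair 1 gave 1.95 (2.87 and 3.27 in the others), but with quantile normalization its difference was -0.73. With a single pair of wide arrays for 1 gene, the narrow range and a rise of rpsB cannot be told apart. A difference in growth between the cultures stays open and was not tested.

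The third pattern is lower sporulation and higher motility genes with AmyQ in stationary phase. The narrow range of 4 of the 9 stationary arrays is argued against, since without them the medians less that of all genes were -1.08 for sporulation regulators, -1.01 for spore coat and 0.70 for flagella, from -1.26, -1.27 and 0.73. Of these arrays only pUB110 replicate 2 and pKTH10 replicate 2 enter the comparison. A narrow array thus stood in each group, which makes this a mild test. Cultures with pKTH10 that had gone less far into stationary phase are a candidate explanation: across 3746 genes outside these lists the AmyQ effect correlated at -0.43 (Spearman -0.34) with the growth phase effect of the mutant, measured on other arrays. These genes still include mmgD, mmgE, ldeG and ldeI of mother-cell metabolism. The correlation therefore cannot part a general delay from an effect on sporulation. Of the 22 lists besides these and CssRS, 13 stood against their growth phase move in the mutant, as a delay predicts, and 9 stood with it (Spearman across these lists -0.164). Less all genes, the TCA cycle (0.67, moved by -2.32 in the growth phase), ribosomal proteins (0.34, -2.36), phosphate starvation (-0.43, 0.75), extracellular proteases (-0.23, 0.99) and siderophore uptake (0.18, -0.88) went as a delay predicts. SigB general stress (-0.41, -0.71), protein quality control (-0.31, -0.87), the SigW list (-0.36, -0.86), glycolysis (-0.24, -1.37) and arginine metabolism (0.23, 0.87) went the other way, and cannibalism toxins stood at -0.01 where the growth phase had moved them by 1.94. A general delay and a specific effect of AmyQ both stay open, and no array measured the cultures' timing.

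For the comparisons of 3 arrays with 3, the 10 possible splits are too few for a share under 0.05. The real split and the highest of the others gave 1 and 2 genes for AmyQ in late exponential phase, 6 and 0 for AmyQ in stationary phase, 0 and 150 for cssS in late exponential phase and 0 and 0 for cssS in stationary phase. They gave 828, 839 and 795 against 0 for growth phase in the 3 strains. The split with 150 genes set wild-type pKTH10 late replicate 1, the array labelled cssS pKTH10 late replicate 1 and mutant late replicate 3 against the rest. This points to a structure among these arrays other than the strains. The split keeps both replicate 1 arrays on the same side, together with mutant late replicate 3, which correlated at 0.642 to 0.674 with the replicate 1 arrays and at 0.873 to 0.902 with the others. No split of 3 against 3 can match the 2 late sets, and their part in this count was not tested. Of the 4 splits that part all 3 pairs, as the real one does, the others gave 0 genes in each of the 3 paired comparisons; those with 2 and 150 genes part 1 pair. For the differences between phases the real split gave 0 genes and the highest of 100 drawn gave 11 and 13; since every split gives at least 0, this decides nothing.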

How the results depend on the processing

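Chosen after the data were seen were the block within growth stages, the term for the late array set, the unnamed spots, the genes near the ceiling, late replicates 2 and 3 alone, stationary pUB110 replicates 1 and 2 as one, the removal of narrow arrays, and the block with quantile normalization. Rescaling to 100 had been in the plan for a table not scaled to its total. Keeping the deposited scaling for the main fit was decided after the data were seen. Of 2783 values of 119 gene results, 2476 kept their direction and side of the threshold, 118 lost it, 176 passed it anew and 13 (9 results) reversed. Of 1200 values of 48 list results, 997 kept both, 192 lost the threshold and 11 (9 results) reversed. Of the 48 list calls 4 held with an estimated correlation. Except where a sentence names one, the cause was not tested.

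Counts of genes past the threshold moved as follows, from 1 for AmyQ late, 6 for AmyQ stationary, 0 for each cssS comparison and each difference by phase, and 828, 839 and 795 for growth phase. Quantile normalization gave 0 for AmyQ late, 41 for AmyQ stationary, 14 for cssS stationary and 1280 for growth with pUB110. Median centring gave 2 for AmyQ late. An offset of 0.02 gave 1 for AmyQ stationary, and one of 0.5 gave 17 there and 1 for cssS stationary. The trended prior gave 0 for AmyQ late. Array weights gave 2160 (238 higher, 1922 lower), 220, 1 for cssS stationary, 339 for AmyQ by phase, 1616 and 2106. Only the compared groups gave 3 for AmyQ stationary, 57 for cssS stationary and 390 for growth with pUB110. The late array set gave 4 and 19 for AmyQ. Rescaling gave 0 and 0 for AmyQ, and 279 and 389 for growth with pKTH10 and in the mutant. Without genes near the ceiling AmyQ late gave 0, since rpsB was among those left out. Late replicates 2 and 3 alone gave 72, 14 and 2 (AmyQ late, AmyQ stationary, cssS late), 17 for AmyQ by phase, and 1288, 1335 and 1250 for growth. Stationary pUB110 replicates 1 and 2 as one gave 2 for AmyQ stationary and 534 for growth with pUB110. Without the narrow arrays both AmyQ counts were 0 and growth gave 170, 366 and 76, with fewer arrays.

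The replicate number as a block over all arrays gave 1, 5, 0 and 0 genes in the strain comparisons and 1052, 1060 and 1016 for growth. In AmyQ stationary it took ldeG to an adjusted p of 0.0548 (0.000604 to 0.974 over its alternatives), and in growth with pKTH10 htrB to 0.0372. As a block within growth stages it gave 3 for AmyQ late, 124 for AmyQ stationary, 0 for cssS late and 28 for cssS stationary, where the lowest correlation within a pair was 0.098 and the samples share only a number; there ykoJ, lonB, mmgD, scoA, cotJB, spaD and spoIVCA passed (adjusted p = 0.0441 each, 0.00299 to 1 over the alternatives). With quantile normalization too, it gave 0, 458, 0 and 234, and 9 for AmyQ by phase. For growth the lowest correlations were -0.143, 0.039 and -0.275. In the paired comparisons the block changed no other call of a named gene or list than those given here and in the results above.

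With single arrays left out the counts ranged from 0 to 20 for AmyQ late (20 without pUB110 late 1), 0 to 227 for AmyQ stationary (227 without pUB110 stationary 3), 0 to 2 for cssS late (2 without the array labelled cssS late 1) and from 375 to 950, 448 to 995 and 453 to 923 for growth. The lowest counts came without pUB110 stationary 1, pKTH10 late 3 and cssS stationary 2, the highest without late replicate 1 of each strain. For cssS stationary and the differences by phase limma called 0 throughout these (218, 284 and 36 at an unadjusted p under 0.05 with all arrays).

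Reversed with quantile normalization, and again with the block added, were rpsB (-0.73), pdhD (-0.88), ahpF (-0.24), sdhB (-0.38) and the glycolysis list (-0.15) for AmyQ late. Without the narrow arrays, which leaves pUB110 late replicate 1 alone in its group, rpsR (-0.27), rplJ (-0.39), icd (-0.14) and tig (-0.22) reversed. So did the direction of the test for the secretion machinery (-0.15), ribosomal (-0.64), surfactin (-0.33) and ATP synthase (-0.34) lists. The medians of the secretion machinery and surfactin lists kept their sign (-0.10 and -0.11 with all arrays). For cssS stationary, with mutant replicate 3 left alone, the ribosomal list reversed (0.033). With single arrays left out the SigB list for cssS late ranged from 0.20 to 0.81 and the test turned to lower without pKTH10 late 1 (0.22) or cssS late 2 (0.20). For cssS stationary it ranged from -0.49 to 0.17 (0.17 without pKTH10 stationary 3). The surfactin list for cssS late ranged from -0.33 to 0.13 (0.13 without pKTH10 late 2), and htrA for cssS by phase from -0.35 to 2.02 (-0.35 without cssS late 2). Signal over background limits dim genes: leaving out the dimmest 25% moved no count beyond 1.5-fold.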

Other observations

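The tests reported here were chosen only after the data were seen. The mutant with pKTH10 was set against the wild type with pUB110, groups that differ in both plasmid and genotype, so that the effects of AmyQ and of the mutation are joined in it. In late exponential phase the CssRS list had a median of 0.56 (adjusted p = 0.00142, and 0.324 with an estimated correlation), which came from the array labelled cssS pKTH10 late replicate 1. By pairs the list stood at 2.69, -0.84 and -0.22, against 0.11, -0.51 and -0.43 for all genes. Without that array the median was -0.39 (adjusted p = 0.675). All lists of bright genes are affected here by the ceiling of the narrow pUB110 late arrays. Protein quality control (0.21, 1.67e-07) and glycolysis (0.22, 0.000175) were higher relative to all genes, and passed with an estimated correlation (0.0438 each), which was lost without the array labelled cssS pKTH10 late replicate 1 (0.165 each). For AmyQ in the wild type, however, glycolysis stood at -0.27 less all genes in pair 1, without a narrow array, and at -0.15 with quantile normalization. Ribosomal proteins (0.46, 4.14e-35) and the TCA cycle (0.87, 1.59e-12) were higher with the preset correlation alone (0.125 and 0.0775 estimated). Of single genes 1 passed (43 at an unadjusted p under 0.05), with a median of all genes of -0.29.

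In stationary phase, less the median of all genes (0.16), the mutant with AmyQ stood below the wild type without it in sporulation regulators (-0.23) and spore coat genes (-0.32). It stood above it in flagella and chemotaxis (0.12) and siderophore uptake (0.34; adjusted p = 0.00155 for each of the 4, and 0.53 with an estimated correlation). General stress genes of SigB had a median of -0.54 (1.12e-16; 0.53). Limma called 0 genes (46 at an unadjusted p under 0.05).

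The 4 brightest of the growth phase genes moved together in stationary phase and apart on some late arrays. On the 9 stationary arrays narH lay between 1.06 and 50.6 percent, sirB between 0.967 and 37.9, ppsC between 0.989 and 36 and yqhQ between 0.73 and 19.6, and the 5 brightest values took up to 48.2 percent of an array's summed signal. On pKTH10 late replicate 1 sirB, ppsC and yqhQ read 4.96, 4.71 and 4.00 percent with narH at 0, and on the array labelled cssS pKTH10 late replicate 1 ppsC read 6.16 percent with the other 3 at 0. Whether the spots lie side by side on the filter is not given in the sources used here, and what ties these signals together was not tested.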
